A study of Mus musculus with 17 samples.

How the data were processed

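The series compares epididymal white adipose tissue of adult male C57BL/6J mice after 13 weeks on a high-fat diet of low (LGI) or high (HGI) glycemic index. Its design text speaks of 19 hybridized arrays, 9 LGI and 10 HGI, of which the authors excluded 2 in quality control, and the 17 others, 8 LGI and 9 HGI, were analysed here. Per the labels, 500 ng of total RNA of each mouse was copied and labelled with both dyes, the Cy3 products were pooled in equal amounts as the reference, and each Cy5 product was hybridized against that pool. Every sample is in Cy5, so a dye effect shared by the arrays cancels in the difference between the diets. The labels number the samples as replicates without saying more of each animal, so p-values measure the spread between these samples.

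The scanner files hold spot intensities, the mean brightness of a spot and the median brightness of its background in each dye, as Agilent Feature Extraction wrote them, per the file headers. The headers give version 9.1.3.1 of that program and the submitters' processing notes give 9.5.1.1. The files also hold processed signal intensities, background-subtracted and dye-normalized by the scanner software, per the file headers, and quality flags per spot. The authors also deposited log2 values for 19836 probes. Their column medians lie between 8.329 and 8.331, their columns correlate at 0.972 to 0.978 with the log2 Cy5 intensities, and the deviations between arrays correlate at 0.38 to 0.85 with those of the log ratios and at -0.18 to 0.073 with those of Cy3. They therefore read as a value for each Cy5 sample, in the direction of Cy5. The scale of their normalization, their centring and their filter are not given in the sources used here, so they served only as an alternative.

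Intensities were analysed in limma 3.58.1 under R 4.3.3, with data.table (version 1.17.8) for reading and Python 3.11.15 with matplotlib 3.10.9 for the plots. Background was corrected by normexp with an offset of 50 over all spots, and log2 ratios of Cy5 to Cy3 were normalized within each array by loess, with control spots and spots with non-uniformity or population outlier flags at weight 0. Of 43790 spots, 2256 were controls and were left out. Flagged spots, 4 to 43 on an array, were left out and saturated ones were kept, except in an alternative that left out the probes with any. Spots of 1 probe were averaged, giving 41174 probes. A probe was tested where its Cy5 signal was well above background on at least 8 arrays, which 25514 probes met, and a gene is represented by its probe with the highest mean intensity over all arrays, which gave 18133 genes. Probes were named through a RefSeq table of assembly GRCm38.p6, used for names only: 23374 by accession, 6733 by symbol and 2919 by an older symbol, while 8148 kept the file's name. The array files name no genome build, so no coordinates are given.

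The diets were compared by limma's linear model and empirical Bayes test (lmFit, eBayes) over all 17 arrays with no covariate, and p was adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The 30 gene lists were tested with camera at its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it, and 154 missing values were set to the group mean for the list tests. An exact permutation test over all 24310 splits of the arrays was added after the data were seen. Design, gene lists, the rule for named genes and most of the other settings tried were fixed before the data were examined. The rule takes 10 higher and 10 lower genes, filled by smallest unadjusted p where too few pass, 2 genes of each list or 4 of a list that passes, and a set of adipose genes named in advance. The 10 higher and 10 lower were taken only from the 14348 tested genes whose symbol is not a clone or model name. Genes named as chosen after their values were seen lie outside the rule. For some list members p was also adjusted over their list alone. This weaker criterion is not part of the fixed design and takes no account of the number of lists.

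The lists cover fatty acid synthesis, triglyceride storage, lipid uptake, fatty acid oxidation, cholesterol synthesis, glucose use, the citrate cycle and respiratory chain, branched-chain amino acid breakdown, brown fat, adipocyte identity, fat mass expansion and insulin signalling. Others hold markers of macrophages, cytokines, T and NK cells, B cells, matrix, endothelium, mesothelium, epididymis and sperm, red blood cells, skeletal muscle and nerve, and genes of the circadian clock, endoplasmic reticulum stress, heat shock, oxidative stress, cell cycle, interferon response and ribosomes. Lists of seminal vesicle secretion, general epithelium, smooth muscle and motile cilia were added after the arrays that stand apart had been seen. 6 of their genes (2 epithelial, 1 of smooth muscle, 3 of cilia) had already appeared in an earlier look at the arrays. The tests were first run with these genes and then again without them, and the values given are from the second run. The lists were measured over genes whose reference signal was well above background on at least 8 arrays.

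The steps were tested on simulated data with the real genes' spread, 8 against 9 arrays and 18133 genes. Of 50 genes changed by 0.3 on the log2 scale 46% were recovered, of 50 changed by 0.5 90%, of 50 changed by 1 88% and of 50 changed by 2 100%, and 12 unchanged genes were called. A list shifted by -0.2 was called, and 0 of the 29 others were. These simulated genes vary independently of one another. All 200 changed genes were in the same simulation, and the large changes ease the Benjamini-Hochberg cut-off for the small ones. The shares recovered therefore do not tell what share of such changes the real comparison would find, where 0 genes passed.

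All arrays were scanned on 1 day. 16 distinct slide numbers were found and 1 array had none, so no known slide held more than 1 array, the slide of 1 array is unknown, and slide could not be used as a block. The Cy5 signal of negative control spots over background was 72.07 to 90.05 on the first 8 arrays scanned (4 LGI, 4 HGI) and 47.06 to 59.64 on the later 9 (4 LGI, 5 HGI), and this scan group was used as a block after it had been seen. HGI 9 and HGI 10 differed from each other with an SD of 0.211 over genes, where pairs of the other 15 arrays have an SD of at least 0.176, so they were kept as separate samples. The lowest correlation between arrays was -0.049. Alternatives covered background correction, normalization, use of the reference, filter, probe rule, variance model, array weights, threshold, tissue covariates, the replicate number, each array left out, arrays with other tissue left out, saturated probes left out, scan group and a fat mass covariate.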

Results

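Gene expression was measured in epididymal white adipose tissue, the fat depot beside the testis, of adult male C57BL/6J mice. The mice had eaten a high-fat diet, with 30% of its energy from fat, for 13 weeks. The carbohydrate of the diet had either a low glycemic index (LGI, 8 mice) or a high glycemic index (HGI, 9 mice), which is a measure of how strongly a carbohydrate raises blood glucose. RNA of each mouse was labelled with the dye Cy5 and hybridized to its own 2-colour Agilent array against a Cy3-labelled pool of all samples. A value is therefore a log2 ratio of a mouse to the pool, and a difference is HGI minus LGI. Between 54.2% and 66.7% of the gene spots of an array were well above background in Cy5, and the number of arrays limits the precision. The comparison asked which transcripts differ in this fat depot with the glycemic index of a high-fat diet.

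Among the 14348 tested genes whose symbol is not a clone or model name, the 4 with the lowest p had lower levels in HGI. They were F3, Agt, Usp7 and Atpaf1. F3, which encodes tissue factor, the starter of blood coagulation, was at -0.33 ± 0.14 (SD, n = 9) in HGI and 0.17 ± 0.21 (SD, n = 8) in LGI, a difference of -0.50 ± 0.08 (SE). Agt, the precursor of angiotensin, differed by -0.59 ± 0.11 and Cp, the copper-carrying ferroxidase ceruloplasmin, by -0.63 ± 0.16. For each of these 3 genes all 9 HGI mice lay below the LGI median. None of the 18133 genes tested passed an adjusted p of 0.05 in limma: 0 were higher and 0 were lower, and F3 came nearest with an adjusted p of 0.152.

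An unadjusted p under 0.05 was reached by 1404 genes, 719 higher and 685 lower, which is 7.74% of the genes where 5% is the share chance gives. Differences were small: 99.5% of genes differed by less than 0.5 on the log2 scale, and the median SE was 0.0807. Leaving out 1 mouse changed the calls among the lower genes. Without LGI 7, whose Cp value of -1.04 lay far below the other LGI mice, 3 genes fell in HGI: Cp by 0.78 (adjusted p = 0.00362), F3 by 0.54 (adjusted p = 0.0188) and Agt by 0.66 (adjusted p = 0.0245). F3 also passed with Cy5 intensities alone, where it fell by 0.58 (adjusted p = 0.0366), and with array weights, where it fell by 0.53 (adjusted p = 0.0327). Over all 39 alternatives the adjusted p ran from 0.0188 to 0.999 for F3, from 0.0245 to 0.999 for Agt and from 0.00362 to 0.999 for Cp.

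**Figure D1:**
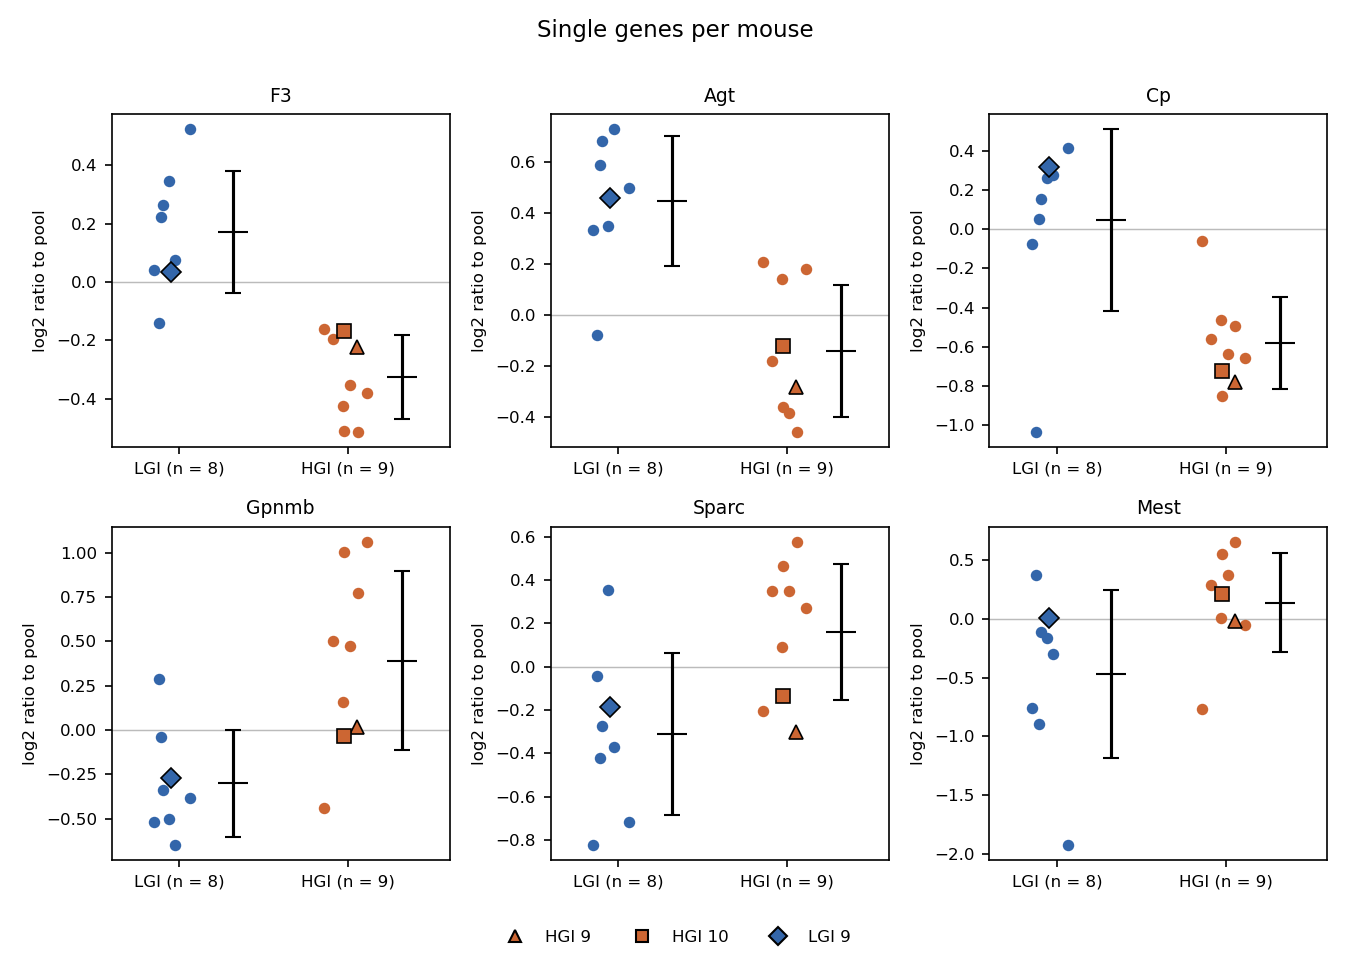
Log2 ratio to the pool (vertical axis) of 6 genes in each mouse on the low (LGI, n = 8) and high (HGI, n = 9) glycemic index diet, with the group mean and SD as a bar beside the points and 3 mice marked by shape. The 9 HGI values of F3 lie between -0.52 and -0.16 and the 8 LGI values between -0.14 and 0.52.

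The other lower genes with the smallest p did not pass the test either. Usp7, which removes ubiquitin from proteins, differed by -0.29 ± 0.06 (SE), Atpaf1, an assembly factor of the mitochondrial ATP synthase, by -0.23 ± 0.05, and Chrdl1, a secreted antagonist of bone morphogenetic proteins, by -0.41 ± 0.10. Pnn differed by -0.42 ± 0.10, Srek1 by -0.34 ± 0.09, Hnrnpa2b1 by -0.29 ± 0.07 and Fip1l1 by -0.28 ± 0.07. A further probe of Atpaf1 and one of Hnrnpa2b1 went the opposite way.

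Among the higher genes, Orm2, an acute-phase plasma protein, differed by 0.42 ± 0.10 (SE), Kif20a, a mitotic kinesin, by 0.33 ± 0.08 and Nusap1, a spindle protein, by 0.31 ± 0.08. Nusap1 was dim: it was well above background on 2 LGI and 7 HGI arrays. The sterol reductase Tm7sf2 differed by 0.29 ± 0.07, the acyltransferase Agpat5 by 0.30 ± 0.07, the vesicle coat protein Sec23a by 0.29 ± 0.07 and Pld3 by 0.28 ± 0.07. Rwdd4a, Trim66 and Fam240b differed by 0.27, 0.26 and 0.26, and Fam240b was well above background on 5 LGI and 7 HGI arrays. The adjusted p of these 10 genes was 0.520. In the first 8 and in the later 9 arrays scanned, which differ in background, F3 differed by -0.50 and -0.50, Agt by -0.54 and -0.64, and Cp by -0.60 and -0.67. These genes were chosen by their p over the same arrays, so a shared sign is no independent check.

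2 HGI arrays stood apart. HGI 9 and HGI 10 correlated at 0.81 with each other and at -0.049 to 0.14 with the other 15 arrays, which correlated with one another at 0.37 to 0.83. Genes of seminal vesicle secretion, chosen after their values were seen, were far higher in them: Svs2 by 6.79 and 6.44 above the median of the other arrays, on the log2 scale. In LGI 9 the ciliated cell regulator Foxj1, named here after its values were seen, was 3.85 above the median of the 14 arrays other than these 3.

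**Figure D2:**
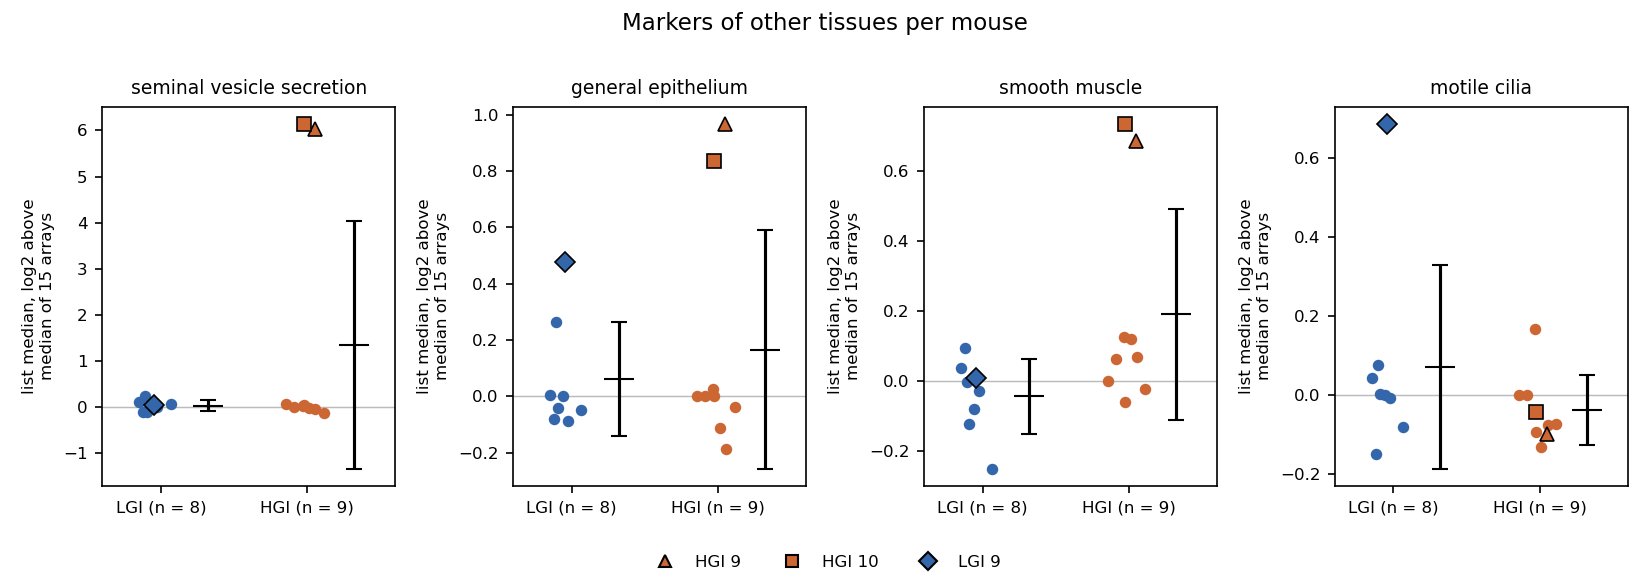
Median over 4 marker lists of other tissues (vertical axis, log2 above the median of the 15 arrays other than HGI 9 and HGI 10) in each LGI (n = 8) and HGI (n = 9) mouse, with group mean and SD as bars. HGI 9 and HGI 10 lie at 6.03 and 6.14 in the seminal vesicle panel, and LGI 9 lies at 0.69 in the motile cilia panel.

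Of 30 gene lists fixed before the data were examined, 13 passed an adjusted p of 0.05 in limma's camera test with its preset correlation: 8 were lower in HGI and 5 were higher. The lower ones were lists of energy and lipid metabolism, adipocyte identity, insulin signalling and mesothelial markers, and the higher ones were lists of macrophage, matrix, endoplasmic reticulum stress, cell cycle and ribosomal genes. With the correlation of each list estimated from the arrays, 0 lists passed, and the smallest adjusted p was 0.246. Fry, which asks whether a list moves on balance in 1 direction, also called 0 lists. An exact two-sided permutation test of each mouse's list mean gave an unadjusted p under 0.05 for 4 lists and for 0 after adjustment (smallest adjusted p = 0.203). The 4 were the citrate cycle (0.0132), branched-chain amino acid (0.0135), insulin (0.0204) and cell cycle lists (0.0275), and the permutation p of the other 9 called lists was 0.0526 to 0.428. In the first 8 arrays scanned 4 of the 13 passed, those of the citrate cycle, branched-chain amino acids, mesothelium and cell cycle, and in the later 9 arrays all but the mesothelial list did. In the 14 arrays whose replicate number occurs in both diets, the triglyceride, oxidation, insulin and ribosomal calls ended, with that number as a block or without.

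The list of the citrate cycle and respiratory chain was lower in HGI by a mean of -0.11, with 27 of its 30 measured members lower (adjusted p = 1.34e-08, and adjusted p = 0.246 with an estimated correlation). Its members did not pass singly. Ppargc1b, a coactivator of mitochondrial biogenesis, differed by -0.31 ± 0.10 (SE), Uqcrc2 of complex III by -0.21 ± 0.07, Sdha of complex II by -0.18 ± 0.07 and Ndufv1 of complex I by -0.14 ± 0.06. The mean shift was -0.09 without HGI 9 and HGI 10, -0.06 in the first 8 and -0.15 in the later 9 arrays scanned.

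All 18 measured genes of branched-chain amino acid breakdown were lower in HGI, by a mean of -0.12 (adjusted p = 3.73e-06, and adjusted p = 0.246 with an estimated correlation). Adjusted over the list alone, 1 member passed: Aldh6a1, of valine breakdown, at -0.29 ± 0.08 (SE). Over all genes it did not pass (adjusted p = 0.520 in limma). Ivd, of leucine breakdown, differed by -0.19 ± 0.08, Bckdhb by -0.18 ± 0.09 and Acad8 by -0.12 ± 0.07. The list mean shifted by -0.10 in the first 8 and by -0.15 in the later 9 arrays scanned and by -0.10 without HGI 9 and HGI 10.

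Fatty acid synthesis genes were lower by a mean of -0.19, 16 of 19 members (adjusted p = 0.00016, and adjusted p = 0.246 with an estimated correlation). Adjusted over the list alone, 3 members passed, but not over all genes (adjusted p = 0.520 in limma for each). Acly, which makes cytosolic acetyl-CoA, differed by -0.59 ± 0.18 (SE). Scd1, the stearoyl-CoA desaturase, differed by -0.40 ± 0.12 and Thrsp, a lipogenic regulator, by -0.40 ± 0.13. Srebf1, a transcription factor of lipogenesis, differed by -0.36 ± 0.14 and Fasn by -0.26 ± 0.18, or -0.17 without LGI 4, and neither passed. The shift was uneven between the scan groups, -0.03 in the first 8 arrays and -0.35 in the later 9, and it was -0.17 without HGI 9 and HGI 10.

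Fatty acid oxidation genes were lower by a mean of -0.06, 15 of 21 members (adjusted p = 0.00563, and adjusted p = 0.307 with an estimated correlation), with Echs1 at -0.20 ± 0.07 (SE), Hadh at -0.23 ± 0.08, Acadvl at -0.19 ± 0.07 and Eci1 at -0.22 ± 0.09. Triglyceride synthesis and storage genes were lower by a mean of -0.08, 15 of 19 members (adjusted p = 0.0058, and adjusted p = 0.378 with an estimated correlation). The lipid droplet coat genes Plin1 and Plin4 differed by -0.22 ± 0.10 and -0.21 ± 0.10, Gpd1 by -0.28 ± 0.16, with a further probe the opposite way, and Mogat2 by 0.47 ± 0.25. The triglyceride list was at 0.02 in the first 8 and at -0.18 in the later 9 arrays scanned, the one called list whose sign differed between them. The oxidation list was at -0.06 and -0.07. Without HGI 9 and HGI 10 both calls ended: the triglyceride list was at -0.01 (adjusted p = 0.482) and the oxidation list at -0.04 (adjusted p = 0.172), with Plin1 at -0.14. Leaving out 1 mouse also ended them: the triglyceride list was at -0.06 without LGI 8 (adjusted p = 0.0517) and -0.05 without HGI 9 (adjusted p = 0.0614), and the oxidation list at -0.05 without LGI 8 (adjusted p = 0.0501). The triglyceride call also ended with array weights (-0.02, adjusted p = 0.183) and with the epididymis and sperm list as a covariate (-0.03, adjusted p = 0.137), and the oxidation call with median centring (-0.02, adjusted p = 0.0762).

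Adipocyte identity and adipokine genes were lower by a mean of -0.11, 15 of 18 members (adjusted p = 0.000197, and adjusted p = 0.246 with an estimated correlation). The transcription factor Cebpa differed by -0.24 ± 0.10 (SE) and the adiponectin receptor gene Adipor2 by -0.23 ± 0.09. Pparg, the master regulator of adipocytes, differed by -0.27 ± 0.13, Adipoq (adiponectin) by -0.16 ± 0.09 and Lep (leptin) by 0.37 ± 0.38, and none of these passed. Lep was at 0.07 without LGI 2, at 0.90 in the first 8 and -0.12 in the later 9 arrays scanned. No difference is given for Cfd (adipsin) and Car3, since the Cy5 spots of the probes used were saturated on 12 and 14 of the 17 arrays. Both are nonetheless counted in the list mean and among its 15 lower members, and a further tested probe of Car3 had the same sign. Without saturated probes the list was at -0.11. The list shifted by -0.02 in the first 8 and by -0.20 in the later 9 arrays scanned. Without HGI 9 and HGI 10 it was at -0.06 (adjusted p = 0.0201, and adjusted p = 0.358 with an estimated correlation), with Cebpa at -0.15, Pparg at -0.16 and Lep at 0.56.

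Insulin signalling genes were lower by a mean of -0.07, 12 of 17 members (adjusted p = 0.0167, and adjusted p = 0.246 with an estimated correlation). Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, differed by -0.37 ± 0.14 (SE), Igf1 by -0.26 ± 0.11, Irs1 by -0.22 ± 0.13, or -0.15 without LGI 2, and Insr, the insulin receptor, by -0.14 ± 0.08, with a further probe of Insr the opposite way. The shift was -0.07 in the first 8 and -0.08 in the later 9 arrays scanned. Without HGI 9 and HGI 10 it was -0.06 and the call ended (adjusted p = 0.154), with Igf1 at -0.15 and Insr at -0.08. It also ended without LGI 8 (-0.07, adjusted p = 0.0517), without HGI 10 (-0.06, adjusted p = 0.0733), with the authors' values (-0.06, adjusted p = 0.164), with median centring (-0.04, adjusted p = 0.0586) and with the macrophage list as a covariate (-0.07, adjusted p = 0.0502). Slc2a4, the insulin-regulated glucose transporter, differed by -0.17 ± 0.12, and by -0.08 without HGI 9 and HGI 10 and -0.11 without LGI 4.

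Mesothelial markers, genes of the layer that covers the fat pad, were lower by a mean of -0.11, 9 of 13 members (adjusted p = 0.00239, and adjusted p = 0.378 with an estimated correlation). The list includes the keratin genes Krt7, Krt8, Krt18 and Krt19, and Krt18 was among the 50 genes LGI 9 raised most in Cy5. Its highest means were those of HGI 9, HGI 10 and LGI 9 (0.256, 0.105 and 0.0877), the arrays with genes of other tissue. The shift may therefore not be of mesothelium alone. Adjusted over the list alone, 2 members passed, Lrrn4 at -0.45 ± 0.13 (SE) and Upk3b at -0.38 ± 0.13. Over all genes neither did (adjusted p = 0.520 in limma for each). Muc16 differed by -0.21 ± 0.10 and Bnc1 by -0.20 ± 0.08. The list shifted by -0.15 in the first 8 and by -0.06 in the later 9 arrays scanned. It was at -0.24 without HGI 9 and HGI 10, at -0.18 without HGI 9 alone and at -0.05 without HGI 2. The call ended in the later 9 arrays (adjusted p = 0.077), with the fat mass expansion list as a covariate (-0.02, adjusted p = 0.0687) and with the macrophage list as a covariate, where the mean was 0.10 (adjusted p = 0.711).

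Macrophage and monocyte markers were higher in HGI by a mean of 0.18, 22 of 24 members (adjusted p = 5.29e-05, and adjusted p = 0.378 with an estimated correlation). Adjusted over the list alone, 4 members passed, but not over all genes (adjusted p = 0.520 in limma for each). Gpnmb, a glycoprotein of lipid-laden macrophages, differed by 0.69 ± 0.18 (SE), the elastase Mmp12 by 0.47 ± 0.13, Mpeg1 by 0.39 ± 0.11 and Cd84 by 0.24 ± 0.07. Mmp12 was well above background on 2 LGI and 7 HGI arrays. Adgre1, the F4/80 antigen, differed by 0.09 ± 0.11, or 0.01 without HGI 4, and the monocyte chemokine Ccl2 by 0.47 ± 0.28, or 0.29 without HGI 3. The list shifted by 0.13 in the first 8 and by 0.23 in the later 9 arrays scanned, and by 0.24 without HGI 9 and HGI 10, with Adgre1 then at 0.17. The call ended in the first 8 arrays (adjusted p = 0.0825).

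Extracellular matrix and fibroblast markers were higher by a mean of 0.10, 19 of 24 members (adjusted p = 0.00942, and adjusted p = 0.552 with an estimated correlation). Sparc, a collagen-binding matrix protein, differed by 0.47 ± 0.15 (SE), Timp1 by 0.40 ± 0.16, or 0.24 without HGI 4, Postn by 0.39 ± 0.15 and Col5a2 by 0.29 ± 0.12. The list shifted by 0.09 in the first 8 and by 0.12 in the later 9 arrays scanned, and by 0.20 without HGI 9 and HGI 10, with Col5a2 then at 0.44. The call ended without HGI 2 (0.09, adjusted p = 0.0501), without HGI 3 (0.07, adjusted p = 0.102), in the first 8 arrays (adjusted p = 0.131) and with the fat mass expansion list as a covariate (0.05, adjusted p = 0.162), and with the macrophage list as a covariate the mean was -0.04 (adjusted p = 0.315). All 14 measured cell cycle genes were higher, by a mean of 0.13 (adjusted p = 0.000732, and adjusted p = 0.246 with an estimated correlation). Birc5 differed by 0.35 ± 0.12, the cyclins Ccnb2 and Ccna2 by 0.25 ± 0.11 and 0.22 ± 0.10, and the replication helicase gene Mcm6 by 0.24 ± 0.10. The cell cycle list shifted by 0.11 in the first 8 and by 0.16 in the later 9 arrays scanned, and by 0.17 without HGI 9 and HGI 10. Its call ended with the macrophage list as a covariate (0.04, adjusted p = 0.496) and with the authors' values (0.07, adjusted p = 0.0866).

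Endoplasmic reticulum stress genes were higher by a mean of 0.17, 17 of 20 members (adjusted p = 0.000245, and adjusted p = 0.378 with an estimated correlation). Sdf2l1 differed by 0.62 ± 0.19 (SE), the chaperone Hspa5 by 0.38 ± 0.14 and Pdia6 by 0.24 ± 0.10, with a further probe of Pdia6 the opposite way, whereas Xbp1, a transcription factor of this response, differed by -0.21 ± 0.09. Ribosomal protein genes were higher by a mean of 0.08, 21 of 24 members (adjusted p = 0.0167, and adjusted p = 0.753 with an estimated correlation), with Rpl10a at 0.22 ± 0.12, Rps19 at 0.18 ± 0.09, Rps6 at 0.17 ± 0.10 and Rpl7 at 0.15 ± 0.09. The stress list shifted by 0.12 and 0.23, and the ribosomal list by 0.07 and 0.10, in the first 8 and the later 9 arrays scanned. The highest means of both lists were those of HGI 9 and HGI 10, 0.39 and 0.26 for stress genes, where the other 15 mice lay below 0. Without them both calls ended: the stress list was at 0.05 (adjusted p = 0.196), with Sdf2l1 at 0.35, Hspa5 at 0.21 and Pdia6 at 0.12, and the ribosomal list turned to -0.03 (adjusted p = 0.196), with Rpl10a at 0.07, Rps19 at 0.08, Rps6 at 0.04 and Rpl7 at 0.05. The ribosomal call also ended without any 1 of LGI 5, LGI 7, LGI 8, HGI 9 and HGI 10, at 0.06, 0.07, 0.07, 0.03 and 0.04, and with Cy5 intensities alone (0.04), array weights (0.02) or the epididymis and sperm list as a covariate (0.02). The stress list was at 0.11 without HGI 9 alone, and its call ended with array weights (0.09, adjusted p = 0.0621).

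**Figure D3:**
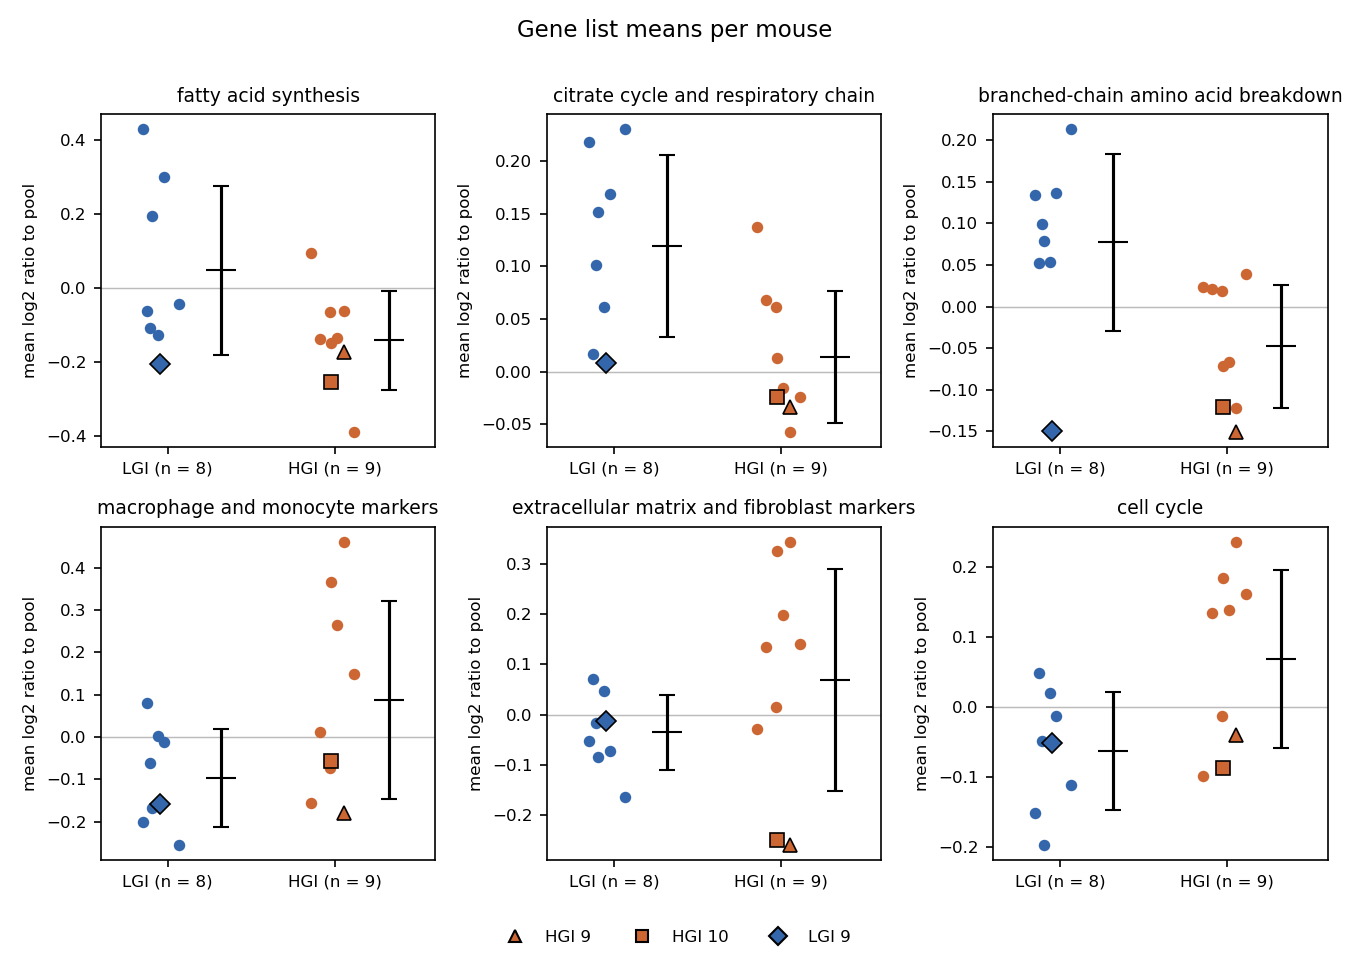
Mean log2 ratio to the pool (vertical axis) over the measured genes of 6 lists in each mouse of the LGI (n = 8) and HGI (n = 9) diets, with group mean and SD as bars and 3 mice marked by shape. In the panel of branched-chain amino acid breakdown LGI 9 lies at -0.15 and the other 7 LGI mice between 0.05 and 0.21.

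Without HGI 9 and HGI 10, 0 genes passed in limma, 1413 had an unadjusted p under 0.05, and 9 lists passed, 8 of them among the 13. With an estimated correlation 0 lists passed without these arrays. The circadian clock list passed without them at -0.09 (adjusted p = 0.0241, and adjusted p = 0.138 with an estimated correlation) but not with all arrays (adjusted p = 0.109). Its adjusted p was 0.0241 to 0.455 over 40 alternatives, and the list passed in 5, among them array weights, the epididymis and sperm list as a covariate and HGI 9 alone left out.

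The other 17 lists did not pass. Fat mass expansion markers shifted by 0.10 (adjusted p = 0.645), with Mest, an imprinted gene tied to adipocyte enlargement, at 0.61 ± 0.24 (SE) and Vegfa at -0.22 ± 0.10. The list was at 0.18 without HGI 9 and HGI 10, but at 0.03 without LGI 2, with Mest then at 0.40. Inflammatory cytokines and chemokines shifted by 0.12 (adjusted p = 0.528), or 0.19 without HGI 9 and HGI 10, with Ccl8 at 0.64 ± 0.30 and Il18 at -0.16 ± 0.07. Without HGI 4 the list was at 0.05 and Ccl8 at 0.41. Lipid uptake and lipolysis genes shifted by -0.01 (adjusted p = 0.342), with the fatty acid binding protein gene Fabp5 at 0.26 ± 0.09, the phosphodiesterase gene Pde3b at -0.23 ± 0.09 and the fatty acid transporter Cd36 at 0.05 ± 0.11, a further probe of which went the opposite way. In the arrays other than HGI 9 and HGI 10 this list was at 0.04 and Cd36 at 0.12, Cd36 turned to -0.04 without LGI 5, and the list passed at -0.04 without LGI 9 (adjusted p = 0.0358). Its member Fabp4 was saturated on all 17 arrays. Glucose uptake and glycolysis genes shifted by -0.02 (adjusted p = 0.319), with Tkt at -0.36 ± 0.15 and Pdha1 at -0.18 ± 0.09, and passed in the later 9 arrays at -0.08 (adjusted p = 0.0125). Oxidative stress genes shifted by less than 0.01 (adjusted p = 0.645), and Gsta4 was at -0.18 ± 0.07. Gpx3, the secreted glutathione peroxidase, was at -0.48 ± 0.13. It passed adjusted over the list alone, but not over all genes (adjusted p = 0.520 in limma). Cholesterol synthesis genes also shifted by less than 0.01 (adjusted p = 0.978), and Acat2 was at -0.21 ± 0.09. Tm7sf2, at 0.29 ± 0.07, passed adjusted over the cholesterol list alone, but not over all genes (adjusted p = 0.520 in limma). This list passed in opposite directions by scan group, at 0.14 in the first 8 arrays (adjusted p = 0.0022) and -0.14 in the later 9 (adjusted p = 0.00107), and at -0.11 with the macrophage list as a covariate (adjusted p = 0.0184). The glycolysis, oxidative stress and cholesterol lists were at -0.01, 0.01 and 0.04 without HGI 9 and HGI 10.

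Among markers of other cells, endothelial genes shifted by -0.04 (adjusted p = 0.342), with Kdr at -0.27 ± 0.09 (SE) and Ptprb at -0.27 ± 0.15, a further probe of which went the opposite way. Without HGI 9 and HGI 10 the endothelial shift was 0.06 and Ptprb was at -0.08, and with the macrophage list as a covariate the list passed at -0.12 (adjusted p = 0.00123), as it did in the first 8 arrays at -0.11 (adjusted p = 0.0225). T and NK cell genes shifted by 0.03 (adjusted p = 0.468), with Gzma, well above background on 3 LGI and 8 HGI arrays, at 0.24 ± 0.10, or 0.16 without HGI 9 and HGI 10, and Cd8b1 at 0.10 ± 0.06. B and plasma cell genes shifted by 0.05 (adjusted p = 0.848), with Blnk at 0.42 ± 0.16, and without HGI 9 and HGI 10 they were at 0.01 and Blnk at 0.23. Epididymis and sperm genes shifted by 0.12 (adjusted p = 0.935), with the protamines Prm1 and Prm2 at -0.48 ± 0.18 and -0.22 ± 0.11, or -0.11 for Prm2 without LGI 9, Prm1 being well above background on 7 LGI and 6 HGI arrays, and skeletal muscle genes by 0.15 (adjusted p = 0.347), with Acta1 at 0.63 ± 0.25 and Myl1 at -0.18 ± 0.09. Both lists had their highest means in HGI 9 and HGI 10, and without them the epididymis and sperm list, which passed at 0.52 with scale normalization between arrays (adjusted p = 0.00594) and was at -0.03 without saturated probes, turned to -0.07, the muscle list was at 0.06 and Acta1 at 0.33. The epididymis and sperm list includes Svs5 and Pate4, genes of seminal vesicle secretion with a saturated spot. They lay 2.52 and 8 above the median of the other 15 arrays in HGI 9, and 2.64 and 7.85 in HGI 10. The height of this list in these arrays, and its use as a covariate, may therefore reflect seminal vesicle genes more than epididymis or sperm. The epididymis and sperm list lay far below the pool in every mouse, at -1.66 and -1.65 in HGI 9 and HGI 10 and -2.61 to -2.2 in the others. Why the pool was so much higher was not tested. Red blood cell genes shifted by 0.13 (adjusted p = 0.57), with Bpgm at 0.71 ± 0.40 and Car1 at 0.12 ± 0.07. Bpgm was among the genes highest in HGI 9 and HGI 10, and without them it was at 0.07 and the list at 0.03. Nerve and glial genes shifted by 0.02 (adjusted p = 0.787), with S100b at 0.17 ± 0.12, or 0.27 without HGI 9 and HGI 10, and Mbp at -0.13 ± 0.09, or -0.08 without LGI 7, a further probe of which went the opposite way.

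The interferon response list shifted by -0.05 (adjusted p = 0.0751), with the RNA sensor gene Ddx58 at -0.30 ± 0.12 (SE), a further probe of which went the opposite way, and Usp18 at 0.24 ± 0.10, and the shift was less than 0.01 without HGI 9 and HGI 10, with these genes at -0.17 and 0.13. The list was at -0.02 without LGI 5. It passed an adjusted p of 0.05 in 9 of its 40 alternatives: with the macrophage list (-0.12, adjusted p = 0.000166) or the fat mass expansion list as a covariate (-0.07, adjusted p = 0.00811), with scan group as a block (-0.05, adjusted p = 0.0499), and without LGI 1 (-0.05), LGI 9 (-0.07), HGI 3 (-0.06), HGI 4 (-0.07), HGI 5 (-0.06) or HGI 6 (-0.06). Heat shock and immediate early genes shifted by 0.02 (adjusted p = 0.645), with Atf3 at 0.17 ± 0.10, or 0.11 without LGI 1, and Hspb1 at 0.20 ± 0.13. They passed in opposite directions by scan group, at -0.11 in the first 8 arrays (adjusted p = 0.00926) and 0.14 in the later 9 (adjusted p = 0.000211). Circadian clock genes shifted by -0.05 (adjusted p = 0.109), with Hlf at -0.12 ± 0.07 and Bhlhe40 at -0.17 ± 0.11, or -0.09 without LGI 9, and brown fat genes by -0.01 (adjusted p = 0.724), with Ebf2 at -0.20 ± 0.09 and Prdm16 at -0.16 ± 0.09. The mean, median and test direction differed in sign for 4 lists, none of them called: cholesterol synthesis, brown fat, B and plasma cell, and oxidative stress genes. Ucp1 was not well above background on enough arrays to be tested, and Pck1 was not analysed here.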

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

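Of the tests below, those on the reference channel, on the diet as the source of gland genes, on the lists without 2 arrays and on the share of adipocytes were chosen only after the result was seen.

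HGI 9 and HGI 10 carried transcripts of the seminal vesicle, an accessory gland of the male tract: the median over 9 of its secretion genes was 6.03 and 6.14 above the other 15 arrays on the log2 scale, where those arrays lay between -0.14 and 0.24 (6.41 and 6.06 without the 5 genes with a saturated spot). 171 of 18484 genes were higher by at least 1 in both than in each other array, and 0 were lower by as much. Against a fault of the reference channel, the deviations of these arrays correlated at 0.82 in Cy5 and at -0.25 in Cy3, and against an effect of the diet shared by HGI mice, the secretion list differed by -0.0323 between the diets over the other 15 arrays (95% interval from exact permutation -0.14 to 0.06; -0.0343 without those 5 genes). RNA of the gland itself may be the source: a gland also brings epithelium and smooth muscle, and the lowest of the 4 medians of those lists in these arrays was 0.686 above the others, with 0.97 and 0.83 for epithelium and 0.69 and 0.73 for smooth muscle. White adipose tissue has smooth muscle of its own in its vessels, and 2 of the secretion genes are also in the epididymis and sperm list.

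LGI 9 carried genes of ciliated epithelium. On a fault of the reference channel, the 50 genes LGI 9 raised most in Cy5 had a median deviation of 2.63 there and of 0.1 in Cy3. They were chosen by their Cy5 deviation, so the first value is high by that choice. Genes shifted mainly in Cy3 were not picked. The test shows that these genes were not shifted alike in Cy3, but it cannot exclude such a fault. RNA of a ciliated duct may be the source: over 19 measured genes of motile cilia LGI 9 lay 0.689 above the other arrays, with 12 of them highest in LGI 9 of all 17 arrays. The next highest list median was that of HGI 1, at 0.166 above the 15 arrays other than HGI 9 and HGI 10. Foxj1 was at 2.29 in LGI 9, 0.488 in HGI 1, -0.151 in LGI 4 and -0.529 in HGI 7, and at -0.825 or less in the rest. Leaving out LGI 9 may therefore not remove all such genes. No explanation from the biology of the fat itself was tested for LGI 9, a single mouse.

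The 13 lists were weighed against chance, these arrays and tissue share. Chance could not be excluded: 10 of 100 splits of the arrays into 8 and 9, the real one included, gave at least 13 lists, the highest other split gave 16, and 93 of the other splits gave at least 1. Most of the splits with at least 13 lists put HGI 9 and HGI 10 in the same group, as the real one does. Among splits of that kind such a count was more frequent than among all splits. Without HGI 9 and HGI 10, 8 of the lists passed and 5 did not, with a median of 109% and 31.3% of the shift kept, but the lists were divided by that same result, so these shares do not decide how far those arrays may be the source, and among the 8 the adipocyte list kept 53.7%. Without and with them the shifts were 0.05 ± 0.04 (SE) and 0.17 ± 0.09 for endoplasmic reticulum stress, -0.03 ± 0.04 and 0.08 ± 0.09 for ribosomal, -0.01 ± 0.06 and -0.08 ± 0.07 for triglyceride, -0.04 ± 0.03 and -0.06 ± 0.03 for oxidation and -0.06 ± 0.03 and -0.07 ± 0.03 for insulin signalling genes. A lower share of adipocytes in HGI cannot be told apart from the diet within cells. If all other cell types rose alike, macrophage and mesothelial genes would rise together, but with a gain of macrophages alone they would not. The difference of these 2 lists was 0.295, with an exact permutation p of 0.189 (0.0309 without HGI 9 and HGI 10, and 0.0571 without LGI 9 as well). It therefore does not decide the question, and the mesothelial list was highest in HGI 9, HGI 10 and LGI 9.

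For single genes past the threshold the splits decide nothing: the real split gave 0 higher and 0 lower in limma, a count that any split reaches (100 of 100 for each), and the highest other gave 1 and 0. Chance could not be excluded for the genes with an unadjusted p under 0.05: 15 of the 100 splits gave at least the 1404 of the real one, and the highest other gave 2837.

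Single mice lay far from the others of their group in 16 of 284 groups of values, by Dixon's ratio of the gap to the range, where chance gives about 14. Values are log2 ratios to the pool. Among leading genes these were Cp in LGI 7 (-1.04, the other LGI mice -0.08 to 0.41) and in HGI 7 (-0.0578, the others -0.85 to -0.46), Pnn in LGI 1 (0.94) and Agpat5 in LGI 7 (0.287). Among lipid and adipose genes they were Lep in LGI 2 (-2.49, the others -0.64 to 0.84), Scd1 in LGI 8 (1.26), Srebf1 in HGI 6 (-0.779) and Mest in HGI 7 (-0.764). Timp1 stood out in HGI 4 (1.33, the others -0.28 to 0.12) and Ddx58 in HGI 10 (-0.928). LGI 9 held 6 of the 16: Fabp5 (-0.435), Blnk (0.245), Prm2 (0.485), Rps6 (0.0673), the lipid uptake list (-0.159) and the list of branched-chain amino acid breakdown (-0.15).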

How the results depend on the processing

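The settings that left out HGI 9, HGI 10 and LGI 9, left out saturated probes, used scan group or fat mass, or tested list means by permutation were chosen only after the result was seen.

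The 20 leading genes kept their direction and call in 433 of 437 values under other settings. F3 made 1 gene lower with Cy5 intensities alone, 1 with array weights and 1 with the fat mass expansion list as a covariate; the cause was not tested. Leaving out each array in turn gave 0 higher genes and 0 to 3 lower ones, 3 only without LGI 7. Of 2455 values of named genes under other settings 2436 were the same in sign and call, and of 1904 with an array left out 1900 were. None of these genes passed with all arrays in the main test, so the call kept is that of not passing. The 20 leading genes were also chosen by their p over the same arrays, so these counts are no independent check.

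The citrate cycle and branched-chain amino acid lists passed under all 23 settings run with camera at its preset correlation, and with each of the 17 arrays left out. Leaving out each array gave 9 to 15 lists, 9 without LGI 8 and 15 without LGI 9. The first 8 arrays scanned gave 7 lists, 4 of them among the 13, and the later 9 gave 15, with 12 of the 13; the cause was not tested. Without saturated probes 13 lists passed. Camera with an estimated correlation gave 0, fry 0 and the permutation of list means 0. Of 685 list values 585 were the same, 40 lost the call, 14 gained it, 40 changed sign without a call and 6 reversed. Cholesterol synthesis was -0.11 with the macrophage list as a covariate and -0.139 in the later 9 arrays against 0.139 in the first 8, matrix genes -0.0379 with that covariate, and heat shock genes -0.112 in the first 8 arrays against 0.145 in the later 9. The mean log2 difference of the list ribosomal proteins was -0.0306 without HGI 9 and HGI 10 and 0.000845 also without LGI 9, with the test direction lower. The cause was not tested.

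The values did not show that replicate numbers pair the samples: same-numbered mice correlated at -0.38 to 0.26, 3 of 7 above 0.1, and 2 of the 7 best with their own number. The labels do not say whether the numbers mark pairs, and so few mice cannot exclude it. The replicate block gave 0 higher genes, 0 lower genes and 9 lists, as did the same 14 arrays without it. Slide as a fixed or random block was not run, since no known slide held more than 1 array and 1 array had no slide number. The share of spots well above background, 54.2% to 66.7%, limits which genes were tested.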

Other observations

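All relations across mice below were chosen only after the lists had been seen.

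Across the 15 mice other than HGI 9 and HGI 10, those with higher fat mass expansion markers had higher macrophage, matrix and cell cycle genes and lower genes of the citrate cycle and respiratory chain. Pearson's r was 0.72 for the macrophage list (permutation p = 0.0027, adjusted p = 0.0072; Spearman's rho = 0.79, permutation p = 0.00086), and 0.72 for the matrix list (permutation p = 0.00251, adjusted p = 0.0072; rho = 0.77, permutation p = 0.00135). It was 0.66 for the cell cycle list (permutation p = 0.00491, adjusted p = 0.00982; rho = 0.78, permutation p = 0.00093) and -0.75 for the citrate cycle list (permutation p = 0.00084, adjusted p = 0.00672; rho = -0.66, permutation p = 0.00934). Without LGI 2 and HGI 7, the mice farthest from the median of the expansion list, r was 0.73, 0.69, 0.71 and -0.65. In the first and the later scan group r was 0.71 and 0.85 for macrophage, 0.76 and 0.74 for matrix, 0.74 and 0.75 for cell cycle and -0.88 and -0.76 for citrate cycle genes. Within LGI and within HGI it was 0.77 and 0.71, 0.75 and 0.72, 0.43 and 0.80, and -0.64 and -0.77. These relations may follow the size of the fat depot of each mouse, which was not analysed here.

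The other 4 of the 8 relations tested did not pass. For inflammatory cytokines r was 0.59 (permutation p = 0.033, adjusted p = 0.0528; rho = 0.54, permutation p = 0.0397), and 0.47 without the farthest mice. For insulin signalling r was -0.31 (permutation p = 0.253, adjusted p = 0.337; rho = -0.56, permutation p = 0.0335), and -0.51 without them. For fatty acid synthesis r was -0.26 (permutation p = 0.35, adjusted p = 0.4; rho = -0.32, permutation p = 0.237), and -0.38 without them. For glycolysis r was -0.033 (permutation p = 0.901, adjusted p = 0.901; rho = 0.039, permutation p = 0.893), and -0.096 without them. In the first and the later scan group r was 0.72 and 0.62 for cytokines, -0.41 and -0.25 for insulin signalling, -0.27 and -0.51 for fatty acid synthesis and 0.41 and -0.51 for glycolysis. All tests were two-sided, with 100000 resamples.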
